A study of Mus musculus with 6 samples.

How the data were processed

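Mouse colon RNA from control mice and from mice with long-term PFOA exposure was sequenced in 6 libraries, 3 per group, made with a SMARTER mRNA-Seq kit per the labels' protocols. The submitters' processing notes name HISAT2, HTSeq and the mm10 build without versions or order. The authors deposited one table of raw read counts per gene with gene identifiers, positions, gene types and functional annotation. Its 6 count columns were matched to the samples by the sample descriptions in the labels, and no other column held values of single libraries. Of its 2033 rows, 1439 carry identifiers of assembled loci, 370 have no reference symbol and 79 merge several gene names. The deposited gene types label 1220 as protein-coding, which is what protein-coding means below. Some coding genes carry other labels, such as Iigp1 (processed pseudogene) and the Hoxa13 row (TEC). Of 1748 rows with a single Ensembl identifier, 1702 matched GENCODE M21 with the version, and coordinates are those of the table. The tool that assembled the loci, strand use in counting, the treatment of multi-mapping reads and the rule that selected the rows are not given in the sources used here. Without a stated strand setting, overlapping and antisense genes (such as those of the Hox clusters) and near-identical family members (such as Cyp2c, Ces1, Ugt2b, Reg3 and globin genes) are uncertain, since their reads can be counted for each other.

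The design was written for a table of all genes, and the table turned out to hold only rows that differ between the groups, so the planned tests were kept with a changed reading. A linear program found library multipliers, each between 0.902 and 1.11, under which all 2033 rows differ at least 2-fold. CPM values are relative to the listed counts of a library, the TMM scaling rests on listed rows, and fold changes are relative to that scaling. The Benjamini-Hochberg adjustment runs over listed rows only (the largest unadjusted and the largest adjusted p are both 0.0408). Camera compares a list with other selected rows. Fry tests a list's own rows against no difference, and every listed row had been selected to differ, so its calls are no evidence of an effect. Sequencing depth is unknown; the listed counts per library range from 1771120 to 2269892, and the 3 most abundant rows take between 12.4% and 30.6% of them.

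Counts were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr kept 1608 rows, TMM factors were computed on them, and glmQLFit with glmQLFTest compared PFOA with control without covariates, two-sided, at an adjusted p of 0.05. The common dispersion was 0.124. The standard error of a log2 fold change is its absolute value divided by the square root of the F statistic. Plain fold values are ratios of summed counts scaled by the TMM-adjusted totals. For a group without any count a floor of 3 counts over the group gives "at least" values, and for a group with 1 to 3 counts a 95% Clopper-Pearson interval is given; both cover counting error only. The 44 gene lists, 23 of pathways and 21 of cell types and tissues, were fixed before the data were examined and hold 1062 gene entries, of which 174 have a row. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01) where at least 5 rows were tested, which held for 14 lists, beside camera with an estimated correlation and fry. Genes were matched to the lists by symbol.

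Named genes followed a rule fixed before the data were examined: among called rows with a descriptive symbol, non-overlapping groups and a mean of at least 1 CPM, the 10 with the largest fold change and the 5 with the smallest p in each direction, and up to 4 members with the smallest p of each list described. Hox cluster rows outside the posterior list, and Muc2, Isx, Cdx2, Osr2, Ly6g, Trgc2, Cyp2d9, Hoxd12, Adipoq, Plin1, Cfd, Sprr1a, Duox2, Ifit3, Igtp and Cidec as a PPAR-alpha example, were named after their values were seen. Some genes that the rule or the lists include are not reported here.

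The edgeR step was tested on simulated counts for 1608 rows: with 200 rows changed, it called 18% of those changed 2-fold, 90% of those changed 4-fold and 4 unchanged rows, and with every row changed by its fitted fold up to a limit, the median error of the log2 fold change was -0.009. Fitted folds beyond the limit, such as those of Hoxb13 and Nts, were cut to it, so the largest folds were not tested at their size. Replicates were compared for duplicates: log2 CPM correlated at 0.951 to 0.984 between replicates of a group, and the smallest chi-square per degree of freedom was 22.4, so that no pair agreed within sampling noise. Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom with and without quality weights, other scalings, other filters, a fold minimum, removal of the 20 most abundant rows, the replicate number as a block, other list tests and each library left out in turn. The scaling that puts all rows at least 2-fold apart and a fit on protein-coding rows were added after seeing the data. Further checks used Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.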

Results

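Colon tissue of mice with long-term exposure to perfluorooctanoic acid (PFOA), a persistent fluorinated surfactant, was compared with colon tissue of control mice by RNA sequencing, with 3 libraries per group. The comparison asked which colon genes differ in expression after the exposure. The labels name 6 frozen mice per group without saying which mice entered which library, and they give no dose, sex or part of the colon, so that p-values measure the spread between libraries. Without a labelled colon part, a difference in position between the groups cannot be told apart from a PFOA effect for any gene. The deposited table lists raw read counts of 2033 gene rows, which summed to 1771120, 1997423 and 2155472 counts in control replicates 1, 2 and 3 and to 2180596, 2136897 and 2269892 counts in PFOA replicates 1, 2 and 3. These sums cover the listed rows only and are not sequencing depths.

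The listed rows had been selected for a difference between the groups. By mean raw count, 1035 rows were higher and 998 rows lower in PFOA, and no row lay between a log2 ratio of -1.08 and 0.92. A set of library multipliers between 0.902 and 1.11 exists under which all 2033 rows differ at least 2-fold. The number of rows past a test is therefore no evidence of an effect here, and a gene without a row is not shown to be unchanged.

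Hoxb13, Hoxd12, Hoxd13 and Evx2, genes of posterior body identity, were nearly absent from the PFOA libraries, while all rows of the fixed lists of PPAR-alpha (peroxisome proliferator-activated receptor alpha) targets and of bile acid and lipid transport were higher there. By direction against all listed rows, neither list passed Fisher's exact test (adjusted p = 0.0831 for each), and 0 fixed lists did. The interferon, T and natural killer cell, adipocyte and red blood cell rows also lay all on one side. Hoxb13, a homeobox gene of the hindgut and tail end of the body, had 9884, 5730 and 7988 counts in the control libraries and 0, 6 and 3 in the PFOA libraries, a log2 fold change of -11.27 ± 0.71 (SE, n = 3 per group; edgeR adjusted p = 4.69e-05). Nts, which encodes the gut peptide neurotensin, had no count in any control library and 173, 399 and 265 counts in the PFOA libraries, at least 288-fold higher against a floor of 3 counts over the control group. Atp12a, the non-gastric proton-potassium pump of the distal colon, was 118-fold lower in PFOA (log2 fold change -6.88 ± 0.42, SE, n = 3 per group; edgeR adjusted p = 4.69e-05).

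Of the 2033 rows, 1608 had counts high enough for edgeR's quasi-likelihood test, and 804 were higher and 804 lower in PFOA at an adjusted p under 0.05. All 1608 tested rows passed, with a largest adjusted p of 0.0408, in a table selected for a difference between the same groups. The largest unadjusted p was 0.0408 too, so every tested row also had to pass when adjusted over its list alone. Such counts per list, given below, only restate the direction of the rows. Along the first principal component of log2 CPM (counts scaled to the listed total of a library), which held 88.2% of the variance, the control libraries lay between -52.72 and -44.08 and the PFOA libraries between 47.5 and 53.33. Such a separation is expected of rows selected for it. PFOA replicate 1 stood apart from its group on the second component (5.6% of the variance), at 23.5 against -11.73 and -12.78 for PFOA replicates 2 and 3.

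**Figure D1:**
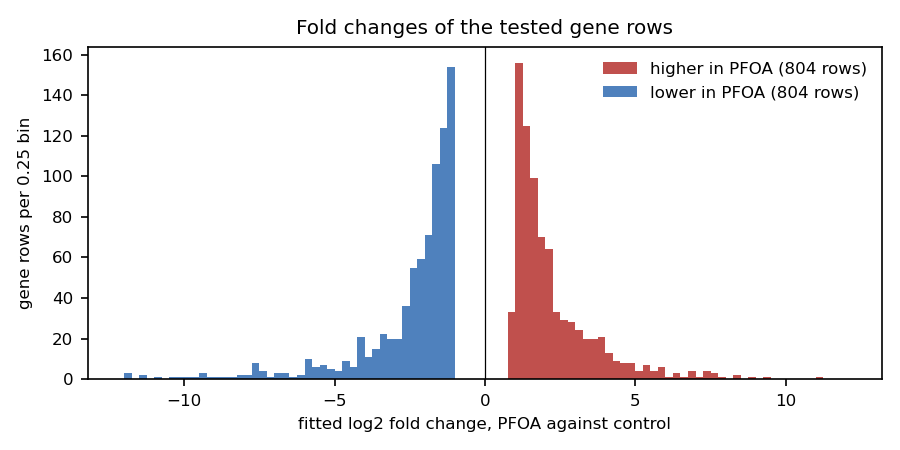
Histogram of the fitted log2 fold change of PFOA against control (x axis) over the 1608 tested gene rows, in bins of 0.25 (y axis, number of rows). The 804 higher and 804 lower rows leave an empty stretch around 0, since the smallest absolute value is 0.962.

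Posterior identity genes, a list of 13 fixed before the data were examined, had 8 listed rows, and all 5 of those tested were lower in PFOA (5 lower and 0 higher over all rows tested, and likewise adjusted over the list alone). Hoxb13 lies on chromosome 11 at 96194316 to 96210066 and Hoxd13, a homeobox gene of the most posterior group, on chromosome 2 at 74667165 to 74671599 (mm10). Hoxd13 had 3297, 345 and 1935 counts in control and 1, 0 and 0 in PFOA, a control-to-PFOA ratio of 5410 with a 95% counting interval from 970.5 to 213705. Its neighbour Evx2, the homeobox gene at the end of the HoxD cluster (chromosome 2, 74652991 to 74659557), had 265, 53 and 138 counts in control and none in PFOA, at least 147-fold lower. A row that merges Hottip, the non-coding RNA at the end of the HoxA cluster, with 2 predicted genes had 201, 352 and 430 counts in control and none in PFOA, at least 318-fold lower. The row of Hoxa13, which is merged with an overlapping gene, was 16.7-fold lower (log2 fold change -4.08 ± 0.31, SE, n = 3 per group; edgeR adjusted p = 7.54e-05). It kept 44, 100 and 75 counts in PFOA. Without control replicate 1, the fitted log2 fold change moved from -11.95 to -11.29 for Hoxd13, from -10.23 to -9.60 for Evx2 and from -7.32 to -5.62 for Hoxd12. Without PFOA replicate 1 it was -13.88 for Hoxd13. Without PFOA replicate 2 it was -12.14 for Hoxb13 and -9.18 for Hoxd12.

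Hox genes of more anterior groups were higher in PFOA in the B and D clusters. A row that merges Hoxb3 to Hoxb6 had 2200, 601 and 711 counts in control and 15000, 17946 and 20619 in PFOA. Hoxb7 had 32, 0 and 6 counts in control and 331, 332 and 391 in PFOA. A row that merges Hoxd3 and Hoxd4 was 13.5-fold higher and Hoxd8 was 7.48-fold higher. Without control replicate 1, the log2 fold change moved from 4.81 to 6.77 for Hoxb7 and from 3.95 to 4.70 for the row of Hoxb3 to Hoxb6. Without control replicate 2 it was 4.19 for Hoxb7. All 4 HoxA rows were lower, with Hoxa9 at 2.96-fold and Hoxa10 at 2.82-fold. All 6 HoxC rows were higher, at no more than 51 counts in any library. They include Hoxc9, Hoxc10 and Hoxc11, the 3 rows of the posterior list that were too low to be tested. Other Hox rows than those of the posterior list were named for belonging to this family, after their values were seen. Camera, which compares a list with the other listed rows, placed the posterior list lower (adjusted p = 0.0426 over 14 lists; adjusted p = 0.501 with an estimated correlation). That call ended when PFOA replicate 1 was left out (camera adjusted p = 0.0705) and with the replicate number as a block (camera adjusted p = 0.0508). It also ended with a filter of 1 CPM in 3 libraries, which brings in the HoxC rows (camera adjusted p = 0.234).

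All 6 listed rows of the PPAR-alpha list, which cover 7 of its 48 target genes of fatty acid oxidation, were higher in PFOA (6 over all rows tested, and 6 adjusted over the list alone). Acaa1b, a peroxisomal thiolase, was 23.5-fold higher (log2 fold change 4.58 ± 0.59, SE, n = 3 per group; edgeR adjusted p = 5.01e-04; 3.93 without PFOA replicate 1). Vnn1, a pantetheinase, was 8.08-fold higher. Mgll, the lipase that splits monoglycerides, was 2.56-fold higher, and Cidec, a lipid droplet protein also counted among the adipocyte markers, was 9.78-fold higher (log2 fold change 3.30, or 3.89 without control replicate 2). Camera placed the list higher than the other listed rows (adjusted p = 0.0426; adjusted p = 0.501 with an estimated correlation). That call ended without control replicate 3 (adjusted p = 0.0512), without PFOA replicate 1 (adjusted p = 0.0705) and with the replicate number as a block (camera adjusted p = 0.0508). It also ended with a filter of 1 CPM in 3 libraries (adjusted p = 0.0732) and on protein-coding rows, an alternative chosen after seeing the data (adjusted p = 0.0699).

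The fixed list of xenobiotic metabolism had 13 listed rows, of which 10 were higher and 3 lower in PFOA, in the same numbers adjusted over the list alone (camera adjusted p = 0.0555; adjusted p = 0.53 with an estimated correlation). Ces1g, a carboxylesterase, had 15, 40 and 32 counts in control and 1869, 2040 and 3005 in PFOA, 81.9-fold higher (log2 fold change 6.34 ± 0.42, SE, n = 3 per group; edgeR adjusted p = 4.69e-05). Cyp2c65, a cytochrome P450, was 56.4-fold higher, and its neighbour Cyp2c66 had a single count in control against 335, 94 and 136 in PFOA, a ratio of 583 with a 95% counting interval from 104 to 23047. Cyp3a25 had no count in control and was at least 27.8-fold higher. A row that merges Ugt2b5 and Ugt2b38, glucuronosyltransferase genes outside the list, was 216-fold higher. The log2 fold change of Cyp2c66 moved from 8.77 to 10.64 without control replicate 2, 8.18 without control replicate 3 and 7.93 without PFOA replicate 1. That of Cyp3a25 moved from 7.77 to 7.16 without PFOA replicate 3. That of the Ugt2b5 row moved from 7.69 to 8.98 without control replicate 2 and 6.98 without control replicate 3. Gsta1, a glutathione transferase, was 9.70-fold lower. These genes belong to families of near-identical copies, so that reads can be shared between their members.

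All 6 listed rows for bile acid, sterol and lipid transport were higher in PFOA (6 also adjusted over the list alone; camera adjusted p = 0.0555; adjusted p = 0.501 with an estimated correlation). Slc51a, a subunit of the transporter that passes bile acids out of enterocytes, had 17, 4 and 2 counts in control and 1363, 1670 and 1458 in PFOA, 201-fold higher (log2 fold change 7.62 ± 0.68, SE, n = 3 per group; edgeR adjusted p = 1.21e-04; 8.83 without control replicate 1). Nr1h4, the bile acid receptor FXR, was 3.28-fold higher, Npc1l1, the cholesterol uptake protein, was 7.22-fold higher, and Slc10a2, the apical bile acid transporter of the ileum, was 3.64-fold higher. Of the 6 listed rows of small intestinal markers, 5 were higher in PFOA and Rbp2, a retinol-binding protein, was lower (camera adjusted p = 0.109; adjusted p = 0.501 with an estimated correlation). Alpi, the intestinal alkaline phosphatase, was 19.0-fold higher. Sis, the brush border sucrase-isomaltase, had 4, 7 and 5 counts in control and 40, 237 and 390 in PFOA, with a log2 fold change of 5.34, or 4.69 without PFOA replicate 3. The libraries in which these metabolic and transport genes were high were also those with the lowest counts of Hoxb13 and Hoxd13. Rows selected for a difference between the groups coincide in this way, so it shows no link between these genes.

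Absorptive colonocyte and ion transport genes went both ways, with 6 rows higher and 11 lower among the 17 tested, in the same numbers adjusted over the list alone (camera adjusted p = 0.293; adjusted p = 0.813 with an estimated correlation). Best2, a bestrophin anion channel, was 7.97-fold lower and Scnn1b, a subunit of the epithelial sodium channel, was 4.26-fold lower, beside the loss of Atp12a counts given above. The enteroendocrine list had 3 rows higher and 4 lower among 7 tested (the same adjusted over the list alone; camera adjusted p = 0.806; adjusted p = 0.884 with an estimated correlation). Insl5, a hormone of colonic L cells, had 959, 1761 and 1582 counts in control and 4, 11 and 18 in PFOA, 126-fold lower (log2 fold change -6.98 ± 0.52, SE, n = 3 per group; edgeR adjusted p = 6.65e-05). Pyy, another L cell hormone, was 8.76-fold lower, while Nts, named above, and Pcsk1, a prohormone convertase, were higher, Pcsk1 by 4.13-fold.

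Epithelial defence genes had 6 rows higher and 2 lower in PFOA, in the same numbers adjusted over the list alone (camera adjusted p = 0.293; adjusted p = 0.813 with an estimated correlation). Reg3b, an antimicrobial lectin, had 61, 5 and 0 counts in control and 14969, 3962 and 1941 in PFOA. The related Reg3g, which lies close by on chromosome 6, had 22, 11 and 2 counts in control and 3538, 876 and 854 in PFOA. Saa3, an acute-phase protein, had 17, 9 and 7 counts in control and 963, 191 and 201 in PFOA. Without PFOA replicate 1, the log2 fold change moved from 8.39 to 6.99 for Reg3b, from 7.32 to 6.13 for Reg3g and from 5.46 to 4.08 for Saa3. It was 11.36 for Reg3b and 8.02 for Reg3g without control replicate 1, and 7.68 and 6.67 without control replicate 3. Sprr1a had 13, 40 and 16 counts in control and 919, 29 and 47 in PFOA. Without PFOA replicate 1 its log2 fold change moved from 3.995 to 0.665 and that of Duox2 from 1.102 to 0.478, and both lost their edgeR call (adjusted p = 0.262 and 0.119). The log2 fold change of Sprr1a was 4.67 without control replicate 2 and 4.60 without PFOA replicate 2. Its call was also lost with limma-voom (adjusted p = 0.133) and with the replicate number as a block (edgeR adjusted p = 0.181). Its call was lost as well without control replicate 1 (edgeR adjusted p = 0.0848) and without control replicate 3 (edgeR adjusted p = 0.0725). That of Duox2 was also lost with DESeq2 (adjusted p = 0.0585), with library totals alone (edgeR adjusted p = 0.077) and with a filter of 1 CPM in 3 libraries (edgeR adjusted p = 0.0517). It was lost as well without control replicates 2 and 3 in turn (edgeR adjusted p = 0.118 and 0.131). Saa1 was 2.76-fold lower and Il18, a cytokine of the epithelium, was 4.51-fold lower. Goblet cell and mucus genes were split, with 6 rows higher, 3 of them of Muc2, and 6 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.97; adjusted p = 0.982 with an estimated correlation). B3gnt6, which builds core 3 mucin sugar chains, was 9.86-fold higher, and Bcas1 and the membrane mucin Muc1 were 3.38-fold and 8.33-fold lower. The gel-forming mucin Muc2, named after its values were seen, is listed as 3 adjacent rows that were 3.05-fold to 3.21-fold higher, and all 3 lost their edgeR call without control replicate 1, at adjusted p = 0.0617, 0.0828 and 0.073. Leaving out control replicate 3 ended the call of 2 of these rows (edgeR adjusted p = 0.0512 and 0.0551), and leaving out PFOA replicate 3 that of the other row (edgeR adjusted p = 0.0544). PFOA replicate 1 had 64916, 18694 and 76380 counts in the 3 Muc2 rows, close to control replicate 2 (64754, 19973 and 75981). The rise lay in PFOA replicates 2 and 3, with 202888 and 237983 counts in the first row.

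Interferon-stimulated genes were higher in PFOA in 6 of 6 rows (6 adjusted over the list alone; camera adjusted p = 0.109; adjusted p = 0.53 with an estimated correlation). Ifit2, an interferon-induced antiviral protein, was 2.84-fold higher. Iigp1, an interferon-inducible GTPase, had 4471 counts in PFOA replicate 1 against 390 and 276 in the other PFOA libraries and 113 to 192 in control. Its log2 fold change moved from 3.74 to 1.18 without PFOA replicate 1 (limma-voom adjusted p = 0.0553 on all libraries). The merged row of Igtp and Irgm2 lost its edgeR call when any control library was left out (adjusted p = 0.0528 to 0.0803) and with the replicate number as a block (edgeR adjusted p = 0.0586). Its log2 fold change moved from 1.65 to 0.600 without PFOA replicate 1. Ifit3 lost its call without control replicate 1, control replicate 2 or PFOA replicate 3 (edgeR adjusted p = 0.0937, 0.0776 and 0.0941). Markers of T cells and natural killer cells were higher in 7 of 7 rows (7 adjusted over the list alone; camera adjusted p = 0.0555; adjusted p = 0.53 with an estimated correlation), at low counts. Gzmb, a granzyme of cytotoxic cells, had 10, 5 and 7 counts in control and 120, 57 and 28 in PFOA (log2 fold change 3.29, or 2.46 without PFOA replicate 1). Nkg7, a cytotoxic granule protein, was 2.58-fold higher.

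Markers of other tissues also differed between the groups. All 7 adipocyte rows were higher in PFOA, 5 of them tested and called, also adjusted over the list alone (camera adjusted p = 0.109; adjusted p = 0.53 with an estimated correlation), with Pparg, the adipocyte master regulator that colonocytes also express, 4.14-fold higher. Adipoq, Plin1, Cfd and Car3 lay above every control library in PFOA replicates 1 and 3 only, with 0, 0, 3 and 7 counts in PFOA replicate 2. The calls of Cfd and Car3 were lost with limma-voom (adjusted p = 0.289 and 0.204) and with the replicate number as a block (edgeR adjusted p = 0.22 and 0.144). They were also lost without control replicate 2, control replicate 3 or PFOA replicate 3, and that of Cfd without control replicate 1 (edgeR adjusted p = 0.0623 to 0.0915). The log2 fold changes of Cfd and Car3 moved from 3.653 and 4.103 to 2.677 and 3.008 without PFOA replicate 3 and to 4.277 and 4.727 without PFOA replicate 2. That of Cfd was 3.005 without control replicate 3, and that of Car3 was 4.963 without control replicate 1. All 6 red blood cell rows were lower, 5 of them tested and called, also adjusted over the list alone (camera adjusted p = 0.062; adjusted p = 0.53 with an estimated correlation), and Hba-a1, an alpha globin, was 6.73-fold lower. The 3 smooth muscle rows, 4 fibroblast rows, 3 endothelial rows and 4 skeletal muscle rows were all lower in PFOA, and Eno3, the muscle enolase, had a log2 fold change of -3.78 ± 0.32 (SE, n = 3 per group). These lists had too few rows for camera. No row was listed for 11 of the 44 lists, namely MHC class II, cholesterol synthesis, the unfolded protein response, the cell cycle, heat shock proteins, the respiratory chain, ribosomal proteins, tuft cells, B cells, plasma cells and sex-linked genes.

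**Figure D2:**
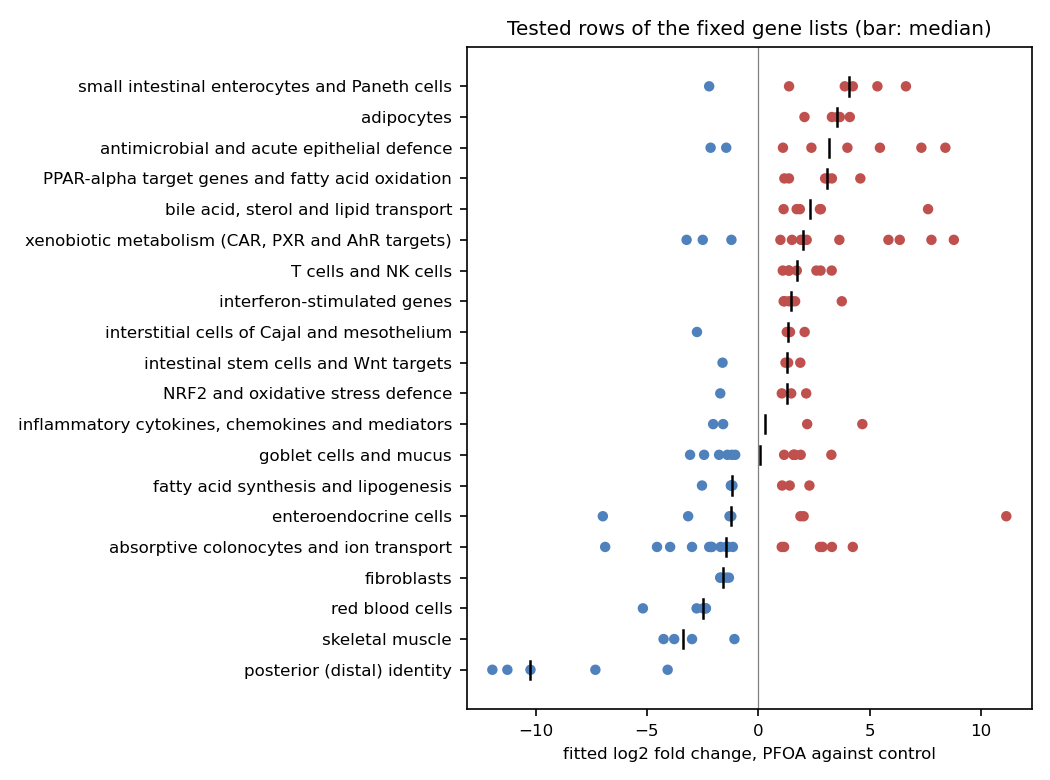
Fitted log2 fold change of PFOA against control (x axis) of the tested rows of each fixed list with at least 4 tested rows (y axis), with a black bar at the median; points of rows with no count in a group, such as Nts and Evx2, depend on the prior of the fit. All 6 rows of the PPAR-alpha list and all 6 of bile acid and lipid transport lie above 0, and all 5 tested posterior identity rows lie below 0.

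Among the single genes with the largest fitted fold changes, Ceacam12 had no count in control and was at least 90.0-fold higher in PFOA, Prap1, a secreted epithelial protein, was 181-fold higher, and Apol10a had 2 counts in control against 180, 174 and 87 in PFOA, a ratio of 227 with a 95% counting interval from 62.6 to 1883. Casp14, a caspase of cornifying epithelium, Klk15, a kallikrein protease, Fxyd4, a regulator of the sodium pump, Tmprss13, a membrane serine protease, and Vtcn1, an immune checkpoint protein, had no count in PFOA and were at least 470-fold, 441-fold, 220-fold, 162-fold and 95.4-fold lower. Control replicate 1 held the most counts of Tmprss13 (339, against 46 and 116) and Vtcn1 (185, against 54 and 56). Without it, their fitted log2 fold changes moved from -10.38 to -9.36 and from -9.62 to -8.83. Those of Apol10a and Prap1 moved from 7.60 and 7.40 to 6.95 and 6.70 without control replicate 3. That of Apol10a moved to 10.19 without control replicate 1 and that of Prap1 to 8.05 without control replicate 2. Sval1 was 725-fold lower, with 3125, 4844 and 4734 counts in control and 8, 2 and 7 in PFOA. The genes with the smallest p-values included, on the lower side, Spink1, a trypsin inhibitor, at 56.2-fold, Pla2g2f, a secreted phospholipase, at 43.1-fold, and a row that merges Pappa2 with an overlapping gene at 62.8-fold. On the higher side they included Amn, the cubilin partner in vitamin B12 uptake, at 18.7-fold, Ces1f at 25.7-fold, B4galnt1, a ganglioside synthase, at 6.25-fold and Plet1, an epithelial progenitor marker, at 54.1-fold.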

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

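All 1608 tested rows passed in edgeR, in a table selected for a difference between the same groups; across the alternatives fixed before the data were examined the number of called rows ranged from 1531 to 2031. DESeq2 called 1922 rows and limma-voom 1587, and leaving out a library gave 1531 (without control replicate 3) to 1663 (without PFOA replicate 1). Of the alternatives chosen after seeing the data, protein-coding rows alone gave 1041, since fewer rows were tested, and the scaling from the 2-fold boundary gave 1608. Of the lists, camera called 2. It called 0 with the correlation estimated per list, 4 with library totals alone and 0 with at least 1 CPM in 3 libraries. On protein-coding rows it called 0 of 12 lists, and the posterior and interferon lists had too few such rows to be tested. Fry called 10, but it tests a list's own rows, all of which had been selected for a difference. The camera calls depend on the setting. Leaving out a library gave 0 called lists (without PFOA replicate 1) to 6 (without PFOA replicate 2), with 5 without control replicate 1, 1 without control replicate 3 and 5 without PFOA replicate 3; apart from the estimated correlation, fewer samples and fewer rows, the cause was not tested. Library totals alone moved the median log2 fold change by -0.204, and the other scalings by -0.052 to 0.048. No tested log2 fold change of the 188 named or listed rows reversed under any of the alternatives run on them. Since these rows had been selected for a difference between the same groups, the absence of reversals says little. Up to 14 of the rows lost their call (without control replicate 3). With the replicate number as a block, 1579 rows and 0 lists were called. Same-numbered libraries correlated in their deviations at 0.114, -0.031 and 0.102, and control replicates 2 and 3 did not correlate best with their own number. Deviations from the mean of 3 libraries cannot decide whether the numbers pair the samples, which stays open. Sequencing depth is unknown, and rows with few counts, such as the HoxC genes, carry wide counting error.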

Other observations

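Apart from those of the fixed lists, all tests below were chosen after the result they bear on had been seen. Transcription factor genes other than Hox genes also differed, named here after their values were seen. Isx, a homeobox gene of the intestinal epithelium, had 67, 822 and 237 counts in control and 11005, 17144 and 14436 in PFOA, a log2 fold change of 5.27 that was 4.63 without control replicate 1 and 6.57 without control replicate 2, and Cdx2, a master regulator of intestinal epithelium, was 4.50-fold higher. Osr2, an odd-skipped zinc finger gene, was 115-fold higher. Ly6g, used as a marker of neutrophils, had 1172, 1999 and 1737 counts in control and 56, 12 and 12 in PFOA, a log2 fold change of -5.83, or -7.13 without PFOA replicate 1, and no other neutrophil marker of the list of 17 had a row.

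Some gene families stood on one side by their counts, with rows too low to be tested included. All 8 Apol rows and all 6 rows of T cell receptor gamma segments were higher in PFOA, with Trgc2 at 10.8-fold, while 7 of 8 Cyp2d rows were lower, with the row of Cyp2d9 at 4.27-fold. Of 221 neighbouring pairs of protein-coding rows within 100000 bases, 169 pairs (76.5%) had the same direction, against 50.0% in 10000 shuffles (permutation p = 0.0001, the smallest they can give). The shuffles treat rows as independent, while the pairs can include split rows of one gene such as Muc2, overlapping rows and near-identical family members. Reads of such rows can be counted for each other, so the share does not show that neighbouring genes are regulated together. Among 270 gene ontology terms with at least 8 rows, 0 passed an adjusted p of 0.05 for direction in Fisher's exact test, and 22 had an unadjusted p under 0.05. The remaining lists with tested rows were small or mixed, by rows called in edgeR: lipogenesis had 3 rows higher and 4 lower (camera adjusted p = 0.788; adjusted p = 0.884 with an estimated correlation), inflammatory mediators 2 and 2 (4 of 6 rows tested), oxidative stress defence 3 and 1, stem cells and Wnt targets 3 and 1, interstitial cells of Cajal and mesothelium 3 and 1, enteric neurons and glia 2 and 1, squamous epithelium 0 and 1 (1 of 3 rows tested), pancreatic acinar cells 0 and 2 (2 of 5 rows tested), junctions 0 and 2, immediate early genes 0 and 2, matrix and fibrosis 0 and 2, the circadian clock 0 and 1, macrophages and dendritic cells 0 and 1, and p53 targets 1 and 0. None of the 3 rows of mast cells and eosinophils had counts high enough for the test.

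The near absence of Hoxb13, Hoxd12, Hoxd13 and Evx2 counts from the PFOA libraries could come from several sources. Less muscle and stroma in the PFOA tissue is argued against for Hoxb13, Hoxd12, Hoxd13 and Evx2, whose median log2 ratio of -9.64 differs by -5.58 from that of Myh2, the lowest of 14 smooth muscle, skeletal muscle, fibroblast and endothelium rows, but stays open for Hoxa13, whose ratio differs from that of Myh2 by -0.01. A more distal part of the colon in the control libraries than in the PFOA libraries stays open: across the 13 Hox rows other than Hoxb13, Hoxd12, Hoxd13 and Hoxa13, the log2 ratio of PFOA to control had no clear relation to the paralogue number (Spearman rho -0.11, Pearson r -0.2, permutation p = 0.71, adjusted p = 0.71 over 3 relations; rho -0.23 without the 2 rows farthest from the median number), and the relations that include these 4 rows (rho -0.83 over the 11 rows of clusters A, B and D and -0.6 over all 17 rows) restate the pattern and carry no weight. The 13 rows include the 6 HoxC rows, which had at most 51 counts in any library. The weak relation over the 13 rows therefore does not argue against a difference in position. Small intestinal markers (5 rows higher and 1 lower) and absorptive colonocyte genes (6 higher and 11 lower) were not part of this relation. An effect of PFOA on the posterior Hox genes at a fixed colon position cannot be told apart from a difference in position. With 0 libraries of a labelled segment, the exposure effect stays untested. The same holds for the other genes that differ between the groups, such as the metabolic, transport and defence genes. Of the 10 splits into 3 and 3 libraries, the real one, with 1608 rows, was the 1 split with as many, and the highest of the others was 0 (8 to 18 rows at an unadjusted p under 0.05 in edgeR); the rows had been selected for the real split and 10 splits allow no share under 0.05, so that this count says nothing on chance.

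Whether colon position varied among the control libraries stays open. Control replicate 1 has the most Hoxd13 (3297 counts) and control replicate 2 the least (345), and across 1608 rows control replicate 1 minus 2 ran against PFOA minus control replicate 3 (Spearman rho -0.216, permutation p = 5e-05, the smallest that the permutations can give; rho -0.223 without Hox, Evx and Hottip rows). Control replicate 3 minus 2 against PFOA minus control replicate 1 gave -0.32, but control replicate 1 minus 3 against PFOA minus control replicate 2 gave -0.025, so that the relation rests on control replicate 2. These are relations across genes within a few libraries, and no biological explanation was tested.

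Adipocyte genes were higher in PFOA in 2 ways. Adipoq, Plin1, Cfd and Car3 lay above every control library in PFOA replicates 1 and 3 and not in PFOA replicate 2, with Adipoq at 54, 0 and 150 counts in the 3 PFOA libraries and 1, 3 and 0 in control, and their ratio of PFOA replicate 1 to 3 spread by 1.32 times, from 0.414 to 0.548. One source such as attached fat tissue in these 2 libraries is a candidate explanation for these 4 genes. It does not account for Cidec, Lpl and Pparg, which in PFOA replicate 2, where Adipoq and Plin1 had no count, were 2.86 to 6.07 times the highest control library. An effect of PFOA on these 3 genes stays open and was not tested.

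PFOA replicate 1 had 54 rows over 4-fold above and 38 rows over 4-fold below the other PFOA libraries, of 1412 rows with at least 100 counts, against 2 to 26 above and 7 to 27 below for the other 5 libraries.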
